A study of Mus musculus with 6 samples.

How the data were processed

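RNA sequencing was carried out on 6 mouse heart libraries, 3 labelled as wild-type control and 3 labelled as TFEB overexpression, all after ligation of the left anterior descending coronary artery. Per the submitters' processing notes, which name tools without saying what each was used for, HISAT2 2.1.0, Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 were run with the mouse build mm10. The authors deposited 1 table of 62498 RefSeq transcripts, each paired with an Entrez gene number, and per the file headers it gives a read count, a TPM and an FPKM for each library. The read counts the authors deposited are estimated counts, not whole numbers, and are not scaled for depth. The TPM values the authors deposited are scaled to the same sum over the transcripts listed in each library. The FPKM values the authors deposited are scaled for transcript length and for depth. The 6 normalised read count columns hold no values and were not used. The strand setting, the annotation release and any filter on transcripts are not given in the sources used here. Where reads of overlapping genes, antisense genes or close paralogues were divided by the authors' quantification, the values of such genes are uncertain.

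From these values, the estimated counts of all transcripts of a gene were summed and rounded to whole numbers, which gave 17524 genes. Symbols and coordinates came from the RefSeq gene table of the same mouse build. Of these genes, 117 had no symbol in it, with 0.510% of all counts, and were kept in the tests under their gene number. The table lists protein-coding transcript models, and mitochondrially encoded genes and the Xist transcript were not analysed here. Totals ran from 12942480 to 14969287 estimated counts per library, so depth differed by 1.16 times at most. Expression is given as CPM, the count of a gene scaled by the library total and its TMM factor, with the SD over the 3 libraries of a group. No interval for counting error is given, since the spread between libraries was used throughout.

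The comparison, TFEB overexpression against control, was fitted with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit, glmQLFTest, two-sided) on 13565 genes. Benjamini-Hochberg adjustment was used over these genes, and a gene was called at an adjusted p under 0.05. Confidence intervals are at 95%. In all, 27 gene lists were written down in advance, and 26 of them had at least 3 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, and with the correlation estimated from the data. Calls are at the preset correlation unless an estimated one is named. Fry, also of limma, was run as a directional and as a mixed test. The 2 groups of 3 libraries can be split in 10 ways, so an exact permutation test of a single value has 0.1 as its smallest two-sided p, and none was run between the groups. No test of annotation terms was run, because the table holds no such columns and no gene was called.

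The genes named were fixed by a rule. Tfeb and Thbs1 are always given. Among called genes with a mean of at least 5 CPM and no overlap between the groups, predicted symbols left out, up to 10 per direction were to be named, filled to 5 by the smallest p where fewer passed. Up to 4 members with the smallest p were taken from each list, and a fixed panel of fibrosis, adhesion, lysosome and cell type genes was added. Genes named beyond this rule were chosen after their values were seen, and this is said where they appear. The groups, the main test, the lists, this rule and the alternatives below, those said to be added apart, were chosen before the data were examined.

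The alternatives were RLE and upper-quartile scaling, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 10 counts in 3 libraries, and limma-trend on log2(TPM + 1), log2(FPKM + 1) and log2(TPM + 0.1) with values of at least 1 in 3 libraries. The test on log2(TPM + 1) was also run with no filter. Each of the 6 libraries was left out in turn, the cardiomyocyte list level was added as a covariate, and the thresholds were varied. The matrix list level, alone or with the level of 4 atrial genes, was added as a covariate after the data were seen, as were camera tests with an estimated correlation in the fits with a library left out or a covariate. The level of a list in a library is the mean log2 CPM of its tested members relative to the mean of the 6 libraries. A sex covariate was not needed, since Y-linked genes were expressed in every library. The analysis was tested on simulated data: counts were drawn for the 13565 genes from the real means, library sizes and dispersions, with 100 genes changed 2-fold and 100 changed 4-fold. The edgeR test recovered 19% of the 2-fold and 79% of the 4-fold genes, with 4 false calls, and DESeq2 recovered 51% and 91% with 47 false calls. Figures were drawn with matplotlib 3.10.9.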

Results

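The series asked how transcription factor EB (TFEB), a master regulator of lysosome and autophagy genes, acts on cardiac fibroblasts after a heart attack. The mice of the TFEB overexpression line carried a TFEB cassette at the Rosa26 locus that Cre recombinase switches on. Cre was driven by the promoter of Acta2, the smooth muscle actin gene that myofibroblasts and smooth muscle express. The controls are labelled as wild type. If they carried neither Cre nor the cassette, effects of these cannot be told apart from those of TFEB. Both groups underwent ligation of the left anterior descending coronary artery. The labels give the tissue as heart and also describe the material as primary fibroblasts. Genes of heart muscle dominated the libraries: Myh6, the main myosin heavy chain of adult mouse cardiomyocytes, stood at 36973 ± 7395 CPM in control and 35791 ± 13032 CPM in TFEB overexpression (SD, n = 3 each). The controls are libraries 35, 36 and 37 and the TFEB overexpression libraries are 34, 41 and 43, after the numbers in their titles. Totals were 14700575, 13948244 and 13308856 estimated counts for the controls and 14969287, 13461420 and 12942480 for TFEB overexpression. The Y-linked gene Ddx3y stood at 118 ± 9.43 CPM in control and 107 ± 6.35 CPM in TFEB overexpression, and was expressed in every library. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these samples. Counts in pairs of libraries within a group differed with a chi-square per degree of freedom of 46.6 to 162, far above counting error. These values argue against repeat sequencing of the same RNA sample. They do not show that the libraries came from separate animals.

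Tfeb itself was slightly higher in the TFEB overexpression libraries, without passing the test. The gene (Entrez 21425, mm10 chromosome 17, 47737037 to 47792416) stood at 34.4, 33.8 and 41.4 CPM in controls 35, 36 and 37, and at 45.4, 45.3 and 39.4 CPM in TFEB libraries 34, 41 and 43. The group means were 36.6 ± 4.20 and 43.3 ± 3.40 CPM (SD, n = 3 each). The log2 fold change was 0.25 (SE 0.12), a ratio of 1.19 with a 95% interval from 0.976 to 1.44, and the edgeR adjusted p was 1.00. Counts for the gene ran from 477 to 713 per library. Whether transcripts from the introduced cassette are counted under the mouse gene is not given in the sources used here.

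No gene passed the edgeR test after adjustment. Of 13565 genes tested, 0 were called higher and 0 lower, and 164 had an unadjusted p under 0.05, of which 51 were higher and 113 lower in TFEB overexpression. An unadjusted p under 0.05 would be reached by 678 genes on average by chance alone. Many genes moved together in these libraries, so such a count varies widely. Other splits of the 6 libraries into 3 and 3 gave from 102 to 3507 genes. DESeq2 called 1 gene, Ddit4, and limma-voom and limma-trend on TPM or FPKM called 0. The 3 values of a group did not overlap those of the other in 645 genes, or 4.75%, where chance gives 10%. Correlations of log2 CPM averaged 0.961 between libraries of a group and 0.966 between libraries of different groups, across genes, which are not independent replicates.

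The genes with the smallest p that met the other parts of the naming rule did not pass the test. Higher in all 3 TFEB libraries than in any control were Kit, a receptor tyrosine kinase of mast cells and progenitors (log2 fold change 1.10, SE 0.21), Acta2 (0.98, SE 0.22), Hes1, a Notch target (0.50, SE 0.12), Id1, a target of BMP signalling (0.35, SE 0.09), and the tubulin gene Tuba1b (0.41, SE 0.11). Acta2 (Entrez 11475, chromosome 19, 34240336 to 34255585), whose promoter drives Cre in this line, stood at 114 ± 20.1 CPM in control and 226 ± 59.6 CPM in TFEB overexpression (SD, n = 3 each). Lower in all 3 TFEB libraries were Ddit4, a stress-induced inhibitor of mTORC1 (−1.32, SE 0.23), Depp1, a FOXO target (−1.21, SE 0.25), the natriuretic peptide receptor gene Npr1 (−0.41, SE 0.09), the kinase gene Sik2 (−0.32, SE 0.08) and the protease inhibitor gene Timp4 (−0.90, SE 0.23). Ddit4 stood at 71.1 ± 4.96 CPM in control and 28.4 ± 9.51 CPM in TFEB overexpression (SD, n = 3 each). Its adjusted p was 0.00898 by DESeq2 and 1.00 by edgeR.

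**Figure D1:**
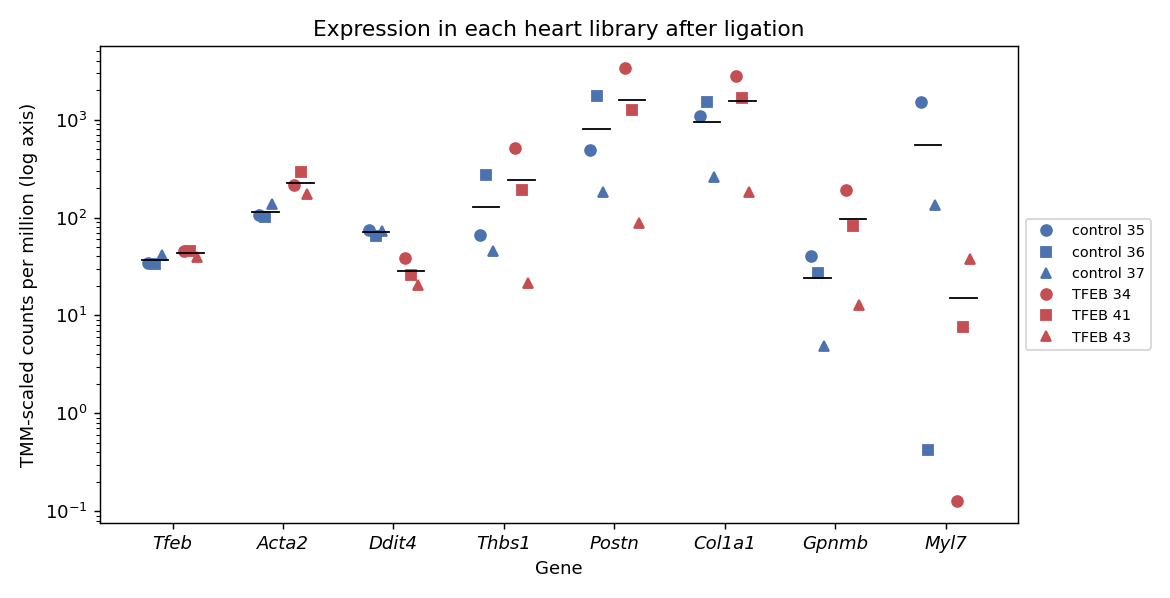
TMM-scaled CPM (log axis) of 8 genes in each of the 6 libraries. Blue marks are the 3 control libraries, red marks the 3 TFEB overexpression libraries, and black lines are group means. Tfeb, Acta2 and Ddit4 lie close together within a group, while Thbs1 runs from 21.5 CPM in TFEB 43 to 517 CPM in TFEB 34 and Myl7 reaches 1507 CPM in control 35.

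Thrombospondin-1, the matrix protein named in the title of the series, varied more between libraries of a group than between the groups. Thbs1 (Entrez 21825, chromosome 2, 118111876 to 118127133) stood at 66.4, 275 and 45.7 CPM in controls 35, 36 and 37, and at 517, 190 and 21.5 CPM in TFEB libraries 34, 41 and 43. The group means were 129 ± 127 and 243 ± 252 CPM (SD, n = 3 each), and the log2 fold change was 0.91 (SE 1.12, edgeR adjusted p = 1.00). The ratio was 1.88 with a 95% interval from 0.290 to 12.2, which excludes neither a strong increase nor a strong decrease. Without TFEB 34 the log2 fold change was −0.29, without control 36 it was 2.12, and limma-voom gave 0.37. In the focal adhesion list, which holds integrins, their matrix ligands and the signalling proteins at their cytoplasmic side, 0 of 123 members passed, 0 adjusted over the list alone, and 87 had a higher value in TFEB overexpression (median log2 fold change 0.08). Both thrombospondin-1 and focal adhesion stand in the title of the series. Whether they were chosen on these samples is not given in the sources used here, so this list is not taken as independent evidence of a direction. Limma's camera gave the list an adjusted p of 0.0789. At the preset correlation it called the list higher without control 36 (adjusted p = 0.00137, median 0.15) and without TFEB 43 (adjusted p = 0.00011, median 0.20). With an estimated correlation it did not (adjusted p of 0.846 and 0.592 with an estimated correlation, and 0.954 over all libraries). Among its members, the integrin gene Itga2b stood at −2.21 (SE 0.68), the growth factor gene Pdgfb at 0.36 (SE 0.15, or 0.23 without control 35), the cyclin gene Ccnd3 at 0.16 (SE 0.08) and Vtn at 0.31 (SE 0.15). The integrin genes Itgb1 (0.11, SE 0.20), Itga5 (0.11, SE 0.25) and Itgav (−0.07, SE 0.37), the focal adhesion kinase gene Ptk2 (0.05, SE 0.12), Pxn (0.07, SE 0.10) and Vcl (0.07, SE 0.11) stood near 0, as did Cd47 (−0.12, SE 0.08) and Cd36 (−0.13, SE 0.25), which encode thrombospondin receptors.

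Matrix and myofibroblast genes followed the same wide spread. Of the collagens and matrix list, 54 of 58 members had a higher value in TFEB overexpression (median log2 fold change 0.37) and 0 passed; of the myofibroblast list, 29 of 31 did (median 0.52) and 0 passed. Adjusted over the list alone, 0 passed in either. Periostin (Postn), made by activated fibroblasts, stood at 489, 1722 and 181 CPM in controls 35, 36 and 37 and at 3366, 1255 and 87.6 CPM in TFEB libraries 34, 41 and 43. Its log2 fold change was 0.98 (SE 1.26). The values were 0.69 (SE 0.98) for Col1a1, 0.36 (SE 0.88) for Col3a1, 0.64 (SE 1.15) for fibronectin (Fn1), 0.32 (SE 0.89) for Ccn2 and 0.18 (SE 0.24) for Tgfb1. Without TFEB 34 they were −0.25 for Postn, −0.035 for Col1a1, −0.29 for Col3a1, −0.51 for Fn1, −1.05 for Ccn2 and −0.050 for Tgfb1. At the preset correlation limma's camera called both lists higher, at an adjusted p of 0.0391 for collagens and matrix and 0.0232 for myofibroblast, and neither with an estimated correlation (adjusted p = 0.954 with an estimated correlation for both). The camera call of the collagens and matrix list also ended under RLE scaling (adjusted p = 0.0589), and those of both lists ended with the cardiomyocyte level as a covariate (adjusted p of 0.668 and 0.208). By limma-voom the medians were 0.21 and 0.30, without control 36 they were 0.86 and 0.91, and without TFEB 34 they were −0.25 and −0.18. At the preset correlation camera still called both lists higher without control 36 or TFEB 43. With an estimated correlation it called neither (camera adjusted p of 0.846 and 0.592 with an estimated correlation). Without TFEB 34 camera at the preset correlation called the collagens and matrix list lower (adjusted p = 0.0287, or adjusted p = 0.901 with an estimated correlation), and it did not call that list without control 35, control 37 or TFEB 41 (adjusted p of 0.0986, 0.555 and 0.514). The myofibroblast list was not called by camera without control 35, control 37, TFEB 34 or TFEB 41 (adjusted p of 0.0612, 0.555, 0.671 and 0.336), and its direction was down without TFEB 34. The level of the collagens and matrix list ran from −1.65 in TFEB 43 to 1.46 in TFEB 34 and from −1.08 in control 37 to 0.85 in control 36. TGF-beta signalling genes had a median of 0.26 (21 of 30 higher, 0 passed) and matrix proteases and their inhibitors 0.10 (18 of 28 higher, 0 passed), with camera adjusted p of 0.224 and 0.884. At the preset correlation camera called the TGF-beta list higher without control 36 or TFEB 43 (adjusted p of 0.0448 and 0.000471), and the protease list lower without TFEB 34 and higher without TFEB 43 (0.0287 and 0.00733). None of these calls held in camera with an estimated correlation (adjusted p of 0.846 and 0.592 for the TGF-beta list and 0.901 and 0.592 for the protease list, with an estimated correlation). The camera direction of the protease list was down, against its median. Neither list had a member that passed when adjusted over the list alone.

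Lysosome genes, the direct targets of TFEB, were on the higher side by small amounts. Of 59 members of the lysosome list, 44 had a higher value in TFEB overexpression, with a median log2 fold change of 0.09, 0 passed, and 0 passed adjusted over the list alone. Without control 36 the median was 0.15. The largest value was that of Gpnmb, a TFEB and MITF target also abundant in macrophages (1.98, SE 1.05), at 24.2 ± 18.1 CPM in control and 95.6 ± 91.1 CPM in TFEB overexpression (SD, n = 3 each). The cathepsin gene Ctsd stood at 0.28 (SE 0.24), Lamp1 at 0.17 (SE 0.13) and the lysosomal calcium channel gene Mcoln1 at −0.07 (SE 0.09). Without TFEB 34 the values were 0.95 for Gpnmb, 0.070 for Ctsd and 0.099 for Lamp1. Without control 35 Gpnmb stood at 2.58, and without control 36 Ctsd stood at 0.44. Limma's camera called the list higher at the preset correlation (adjusted p = 0.0391) and not with an estimated one (adjusted p = 0.954 with an estimated correlation). Its level moved with the matrix genes, from 0.39 in TFEB 34 to −0.29 in TFEB 43 and −0.32 in control 37. Without TFEB 34, or without control 37, camera did not call the list (adjusted p of 0.275 and 0.923) and its direction was down. It called the list at the preset correlation without control 35, control 36, TFEB 41 or TFEB 43 (adjusted p of 0.00168, 0.00889, 0.0225 and 4.9e-05), and not with the cardiomyocyte level as a covariate (0.668). With an estimated correlation camera did not call it in any of these 4 fits (adjusted p of 0.891, 0.846, 0.973 and 0.592 with an estimated correlation). V-ATPase genes, which acidify the lysosome, had a median of 0.05 (16 of 19 higher, camera adjusted p = 0.121), autophagy genes −0.02 (13 of 43 higher, 0.224) and the MiT/TFE family with its Rag and folliculin partners 0.04 (14 of 20 higher, 0.497). At the preset correlation camera called V-ATPase higher without TFEB 41 (adjusted p = 0.0397) and autophagy lower without TFEB 43 (0.0197), and neither with an estimated correlation (adjusted p of 0.973 and 0.592 with an estimated correlation). No member of these 3 lists passed, over all genes or adjusted over the list alone. Sqstm1 (−0.01, SE 0.16), Map1lc3b (−0.06, SE 0.12), Flcn (−0.06, SE 0.12), Rragd (−0.02, SE 0.17) and Ppargc1a (0.02, SE 0.28), all known TFEB targets, stood near 0. Cre is driven by the Acta2 promoter, while genes of heart muscle dominated these libraries. Values near 0 therefore do not exclude a change confined to cells that express Acta2.

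Markers of other cell types showed no member that passed, either over all genes or adjusted over the list alone. Fibroblast markers had a lower value in 17 of 24 members (median log2 fold change −0.18, or −0.037 without control 35). Among them were Scara5 (−0.85, SE 0.33), Lamc3 (−1.60, SE 0.61) and the complement gene C3 (−0.76, SE 0.35, or −0.45 without control 36). Pdgfra stood at −0.15 (SE 0.22). Smooth muscle and pericyte markers had a higher value in 17 of 20 (median 0.22, or 0.091 without control 35), with Acta2 the farthest from 0. Mesothelial, Schwann and adipocyte markers had a lower value in 16 of 17 (median −1.63). That median was −0.56 by limma-voom and −0.74 on log2(TPM + 1). In that list the adipocyte genes Adipoq (−4.15, SE 1.25), Cidec (−4.17, SE 1.21), Plin1 (−3.42, SE 1.13) and Cfd (−4.17, SE 1.398) had the smallest p. Without control 36 Plin1 stood at −1.76 and Cfd at −2.21. Adipoq stood at 11.1, 29.5 and 2.10035 CPM in controls 35, 36 and 37 and at 0, 1.61 and 0.826 CPM in TFEB 34, 41 and 43. Limma's camera called these 3 lists at the preset correlation, at adjusted p of 0.0391, 0.0232 and 0.00155, and none of them with an estimated correlation (adjusted p = 0.954 with an estimated correlation for each). The camera call of the fibroblast list ended without control 35 or TFEB 43 (adjusted p of 0.261 and 0.845). That of the smooth muscle list ended without control 35, TFEB 34 or TFEB 41 (camera adjusted p of 0.509, 0.275 and 0.063). That of the mesothelial, Schwann and adipocyte list ended without control 35 (camera adjusted p = 0.0612). Macrophage and monocyte markers had a median of 0.34 (20 of 25 higher, camera adjusted p = 0.121), with Cd68 at 0.63 (SE 0.49), Spp1 at 1.59 (SE 0.93) and the resident macrophage gene Cd163 at −0.70 (SE 0.25). Without TFEB 34 Cd68 stood at 0.074 and Spp1 at 1.05, and without TFEB 43 they stood at 0.94 and 2.098. At the preset correlation camera called the macrophage list higher without control 36 or TFEB 43 (adjusted p of 0.00812 and 0.000111), and not with an estimated correlation (adjusted p of 0.846 and 0.592 with an estimated correlation). Endothelial markers had a median of −0.05 (8 of 22 higher, camera adjusted p = 0.435), with Pecam1 at −0.15 (SE 0.10). Cardiomyocyte markers had a median of 0.04 but a mean of −0.09, with Tnnt2 at −0.01 (SE 0.27) and Myh6 at −0.05 (SE 0.47), and a camera adjusted p of 0.497 with direction up. Without TFEB 34 the preset correlation gave that list an adjusted p of 0.00279 in camera and an estimated one did not call it (adjusted p = 0.901 with an estimated correlation). Neutrophil markers had a median of −0.22 (2 of 6 higher), lymphocyte markers −0.30 (2 of 6), red blood cell markers −0.06 (1 of 6) and Y-linked genes −0.13 (1 of 4), with camera adjusted p of 0.949, 0.903, 0.884 and 0.121. For the lymphocyte and red blood cell lists the camera direction was up, against the median and the mean, and without control 37 camera called the red blood cell list higher at the preset correlation (adjusted p = 0.00731) and not with an estimated one (adjusted p = 0.996 with an estimated correlation). The direction of 3 of these medians depended on the method: the neutrophil median was 0.12 by limma-voom, the lymphocyte median 0.28 by DESeq2 and 0.27 with no filter, and the red blood cell median 0.019 on log2(TPM + 1).

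Metabolic and stress genes differed little between the groups, and none passed, either over all genes or adjusted over the list alone. Fatty acid oxidation genes had a lower value in 26 of 28 members, with a median log2 fold change of −0.10, or −0.15 without control 35. Decr1 stood at −0.22 (SE 0.34) and Mlycd at −0.20 (SE 0.34), or at 0.050 and 0.054 without TFEB 34 and −0.61 and −0.65 without TFEB 43. Limma's camera called this list lower at the preset correlation (adjusted p = 0.0232) and not with an estimated one (adjusted p = 0.954 with an estimated correlation), nor with the cardiomyocyte level as a covariate (adjusted p = 0.380). Camera did not call it without control 37, TFEB 34 or TFEB 41 (adjusted p of 0.856, 0.116 and 0.0639), and its direction was up without TFEB 34. At the preset correlation camera still called it lower without control 35, control 36 or TFEB 43. With an estimated correlation it did not (camera adjusted p of 0.891, 0.846 and 0.592 with an estimated correlation). The level of the list was −0.66 in TFEB 34 and 0.53 in TFEB 43, opposite to that of the matrix genes. Oxidative phosphorylation genes had a median of −0.04 (4 of 47 higher, camera adjusted p = 0.130), hypoxia and glycolysis genes 0.09 (18 of 28 higher, 0.0705), and interferon response genes −0.08 (9 of 26 higher, 0.121). The medians were 0.14 for cytokines and chemokines (14 of 25 higher, mean −0.01, camera direction down, 0.884), 0.01 for cell cycle genes (22 of 41 higher, 0.887) and 0.07 for immediate-early and stress genes (15 of 22 higher, 0.497). Left-out libraries moved several of these camera calls at the preset correlation. None of the calls in the next sentences held with an estimated correlation, where the lowest camera adjusted p for any list was 0.891 without control 35, 0.846 without control 36, 0.901 without TFEB 34, 0.973 without TFEB 41 and 0.592 without TFEB 43. Interferon response was called lower without control 35, TFEB 34 or TFEB 41 (adjusted p of 1.3e-09, 0.00275 and 0.0429), with medians of −0.22 and −0.21 without control 35 and TFEB 34, and of 0.031 without control 36 and 0.059 without TFEB 43. Oxidative phosphorylation was called lower without control 36, TFEB 41 or TFEB 43 (0.00302, 0.0397 and 3.7e-07) and higher without TFEB 34 (1.7e-05). Cell cycle genes were called lower without TFEB 34 and higher without TFEB 43 (0.0171 and 0.000168), cytokines and chemokines lower without TFEB 41 (0.0225), hypoxia and glycolysis higher without control 36 (0.00302), and the immediate-early list higher without control 36 or TFEB 43 (0.0393 and 0.00600). The median of the cell cycle genes was −0.058 by limma-voom, and that of the oxidative phosphorylation genes was 0.071 with the cardiomyocyte level as a covariate. In the immediate-early list Dusp1 stood at −0.52 (SE 0.16) and Ier2 at 0.35 (SE 0.13), both without overlap between the groups.

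**Figure D2:**
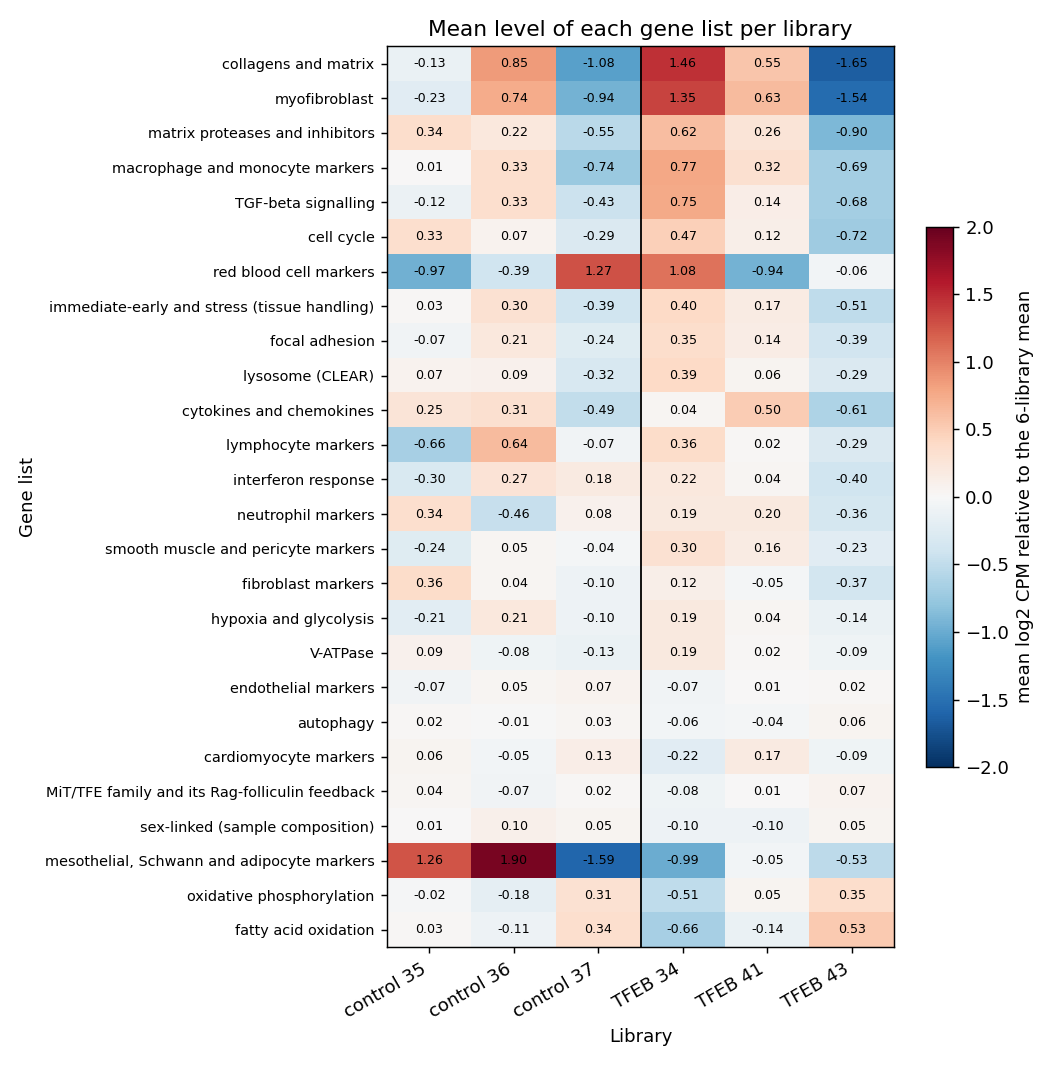
Mean log2 CPM of each of 26 gene lists in each library, relative to the mean of the 6 libraries, with the 3 controls to the left of the black line and the 3 TFEB overexpression libraries to the right. The collagens and matrix list ranges from −1.65 in TFEB 43 to 1.46 in TFEB 34, and both groups hold libraries above and below 0.

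The libraries differed along axes that crossed the groups. The leading principal component of log2 CPM held 57.7% of the variance and placed TFEB 34 at 49.9, control 36 at 29.6, TFEB 41 at 13.8, control 35 at −7.88, control 37 at −36.9 and TFEB 43 at −48.5. The next component held 19.6% and set control 35 (−44.9) apart from the rest, which lay between 4.96 and 16.0. Control 35 carried the atrial muscle genes Myl7 at 1507 CPM, Myl4 at 1953 CPM and Sln at 632 CPM, of which Myl4 and Sln were chosen after their values were seen. In control 37, the library with the next highest values, they stood at 134, 182 and 48.4 CPM. Without control 35, edgeR called 0 genes, and camera at the preset correlation called 3 lists, 2 of the 7 called over all libraries and interferon response. Without TFEB 34 the median log2 fold change was −0.066 for the lysosome list, −0.017 for focal adhesion, −0.14 for TGF-beta signalling, −0.21 for matrix proteases, −0.088 for macrophage markers, −0.070 for cytokines and chemokines, −0.37 for cell cycle genes, 0.16 for oxidative phosphorylation and 0.14 for fatty acid oxidation, each of the opposite sign to the value over all libraries. Camera called 13 lists without control 36, 4 without control 37, 8 without TFEB 34, 7 without TFEB 41 and 14 without TFEB 43. Of these, 7, 3, 3, 3 and 6 were among the 7, whatever their direction. Without TFEB 34 the collagens and matrix list was called lower, while over all libraries it was called higher. With an estimated correlation camera called 0 lists in each of these 6 fits (lowest adjusted p = 0.253, without control 37).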

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

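The fits with the matrix level, or the matrix and atrial levels, as covariates were chosen after the results were seen; the other alternatives were planned. edgeR and limma called 0 genes under each of their alternatives, at thresholds of 0.01, 2-fold and glmTreat against 1.5-fold, and without the sex chromosomes, and DESeq2 called 1, Ddit4. At an unadjusted p under 0.05 there were 164 genes in edgeR, 262 by DESeq2, 289 with no filter, 281 on log2(TPM + 1) with no filter, 99 with the cardiomyocyte covariate, 519 with the matrix covariate and 494 with both covariates. Leaving out a library gave 97 without control 35, 407 without control 36, 263 without control 37, 231 without TFEB 34, 88 without TFEB 41 and 581 without TFEB 43. No paired analysis was possible because the groups share no replicate numbers. The alternative without mitochondrially encoded genes was not run, since it would remove no gene. Camera called 7 lists at the preset correlation, 0 with an estimated correlation, 0 by the directional and 0 by the mixed fry test, 6 with RLE scaling, 7 with the filter of 10 counts, 3 with the cardiomyocyte covariate, 5 with the matrix covariate, 4 with both added covariates and from 3 to 14 when a library was left out. With the matrix covariate, with and without the atrial level, the call of the smooth muscle list ended. The call of the lysosome list ended with the matrix covariate alone. The myofibroblast list shares members with the covariate, and the covariate is the level of the collagens and matrix list. What these fits give for the myofibroblast and the collagens and matrix lists therefore decides nothing. With both levels the calls of the fibroblast and the mesothelial, Schwann and adipocyte lists ended too. Both fits newly called macrophage markers higher (camera adjusted p of 0.0261 and 0.0127) and interferon response lower (0.0261 and 7.2e-07) at the preset correlation. With an estimated correlation, also chosen after the results were seen for these fits, camera called 0 lists when a library was left out (lowest adjusted p = 0.253), 0 with the cardiomyocyte covariate (0.973), 0 with the matrix covariate (0.953) and 0 with both added covariates (0.894). Of list medians, 31 of 156 changed sign in 20 lists when a library was left out, 20 of 286 in 5 lists under the other alternatives written down in advance and 6 of 52 with the added covariates. Tfeb kept its direction throughout, with log2 fold changes from 0.19 to 0.35. Thbs1 ran from −0.29 to 2.12 when a library was left out and stood at 0.070 with the matrix covariate and −0.089 with both added covariates. Of 722 values of 38 other genes under 19 alternatives, 665 kept their sign and side of the threshold, 56 in 18 genes changed sign and 1 was called; apart from Ccn2, Col1a1, Col3a1, Postn and Fn1, these 18 genes had values near 0. Ccn2 stood at −0.22 by limma-voom, −0.15 on log2(TPM + 1) with or without the filter, −0.16 on FPKM and on log2(TPM + 0.1), −0.20 with the cardiomyocyte covariate, −0.40 with the matrix covariate and −0.20 with both. Ppargc1a stood at −0.031 by limma-voom, −0.034 on log2(TPM + 1) with or without the filter, −0.043 on FPKM and −0.036 on log2(TPM + 0.1). With the cardiomyocyte covariate Myh6 was 0.084 and Tnnt2 0.089; with the matrix covariate Col1a1 was −0.029, Fn1 −0.041, Col3a1 −0.19 and Tnnt2 0.026. With both covariates Postn was −0.024, Itgb1 −0.0069, Ptk2 −0.031, Flcn 0.061, Itga5 −0.039, Rragd 0.036, Myh6 0.013 and Tnnt2 0.053. Thbs1, Ccn2, Col1a1, Col3a1, Fn1 and Postn belong to the list whose level is the matrix covariate, and Myh6 and Tnnt2 to the cardiomyocyte list. When a library was left out, log2 fold changes ran for Ptk2 from −0.025 to 0.13, Flcn from −0.13 to 0.054, Itgav from −0.42 to 0.20, Rragd from −0.20 to 0.090, Sqstm1 from −0.18 to 0.078, Ppargc1a from −0.32 to 0.25, Col3a1 from −0.29 to 0.86, Ccn2 from −1.05 to 0.81, Myh6 from −0.35 to 0.19, Tnnt2 from −0.14 to 0.13, Postn from −0.25 to 2.23, Tgfb1 from −0.050 to 0.37, Col1a1 from −0.035 to 1.22, Fn1 from −0.51 to 1.58, Itgb1 from −0.070 to 0.24, Cd36 from −0.37 to 0.053, Itga5 from −0.12 to 0.32 and Pdgfra from −0.35 to 0.00060. The cause of these reversals was not tested, except that leaving out a library lowers the number of samples. On simulated counts with the dispersions of these libraries, edgeR recovered 19% of genes changed 2-fold and 79% of those changed 4-fold. Changes near 2-fold could thus be missed in most genes. Each gene was drawn independently there, while many genes of the real libraries moved together. The simulation therefore does not show that real changes of 4-fold would be called. Adipoq, with a fitted log2 fold change of −4.15, was not called by edgeR.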

Other observations

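The tests of genotype, of scar and muscle shares, of both explanations for the atrial genes, of the Rosa26 neighbourhood and of the lysosome list with added covariates were chosen only after the result they address was seen, as were the correlations of lists other than oxidative phosphorylation with the matrix list. Apart from the adipocyte genes, the mesothelial genes Msln and Upk3b, which mark the outer lining of the heart and were chosen after their values were seen, were highest in controls 35 and 36 and lowest in control 37. Msln stood at 51.8, 74.8 and 0.389 CPM in controls 35, 36 and 37 and at 24.3, 9.15 and 10.8 CPM in TFEB 34, 41 and 43, and Upk3b at 34.4, 63.1 and 0.622 CPM against 7.51, 7.98 and 9.92 CPM. Red blood cell genes varied independently of the groups, with list levels of 1.27 in control 37 and 1.08 in TFEB 34 against −0.97 in control 35 and −0.94 in TFEB 41. One of 5 listed Tfeb transcript models, chosen after its values were seen, had estimated counts of 60.7, 134 and 96.9 in controls 35, 36 and 37 and of 231, 219 and 107 in TFEB 34, 41 and 43. The most abundant model did not follow it, with 349, 318 and 321 against 331, 267 and 370, and another had 103, 28.4 and 114 against 149, 128 and 0.

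The matrix genes differed more between libraries of one group than between the groups, over a range of 3.10 on the log2 scale. Totals differed by 1.16 times only, which argues against depth as the source. Thinning every library to the smallest total left a range of 3.10. With totals so alike, thinning could change little, so its result adds no support. The group means differed by 0.24, with within-group SDs of 0.96 and 1.59. The level ran from −1.08 to 0.85 within control and from −1.65 to 1.46 within TFEB overexpression, and libraries of a group share their genotype label. A label shared within a group cannot give spread within that group, whatever the values, so these values are no test of it. Whether genotype shifts the level between the groups is not decided. Different shares of scar and muscle in the tissue taken may contribute but were not decided: the matrix level went against oxidative phosphorylation genes over the 6 libraries, with Pearson's r = −0.935 (exact permutation p = 0.00972, adjusted over 10 relations 0.0194), Spearman's rho = −0.943 (exact permutation p = 0.0167, adjusted 0.0417) and r = −0.842 without the 2 libraries farthest from the median, while cardiomyocyte markers, which include fetal and atrial genes, did not mirror it, at r = −0.296 (exact permutation p = 0.558, adjusted 0.620), rho = −0.257 (exact permutation p = 0.658, adjusted 0.658) and r = −0.749 without those 2 libraries. The cardiomyocyte list holds Myl7, which ran from 0.127 CPM in TFEB 34 to 1507 CPM in control 35. It also holds Nppb, Ankrd1 and Myh7, singled out after their values were seen, which were highest in TFEB 34. Its weak relation to the matrix level therefore does not argue against different muscle shares. The same level was the cardiomyocyte covariate, so those fits do not cleanly adjust for muscle content. Infarct size and the part of the heart taken are not given in the sources used here, so infarct size and dissection stay open.

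The other 8 relations to the matrix level in the same family of 10 were as follows. Thbs1 went with the matrix list computed without it, at Pearson's r = 0.986 (exact permutation p = 0.0014, the smallest 6 libraries can give; adjusted 0.00694), Spearman's rho = 1 (exact permutation p = 0.00278, adjusted 0.0139) and r = 0.994 without the 2 libraries farthest from the median. Focal adhesion genes not in the matrix list went with it at r = 0.991 (exact permutation p = 0.0014, adjusted 0.00694), rho = 1 (exact permutation p = 0.00278, adjusted 0.0139) and r = 0.996 without those 2 libraries, and lysosome genes at r = 0.944 (exact permutation p = 0.00833, adjusted 0.0194), rho = 0.886 (exact permutation p = 0.0333, adjusted 0.0667) and r = 0.814. Macrophage markers went with it at r = 0.979 (exact permutation p = 0.00417, adjusted 0.0139), rho = 0.943 (exact permutation p = 0.0167, adjusted 0.0417) and r = 0.975 without those 2 libraries. Fibroblast markers did not, at r = 0.277 (exact permutation p = 0.654, adjusted 0.654) and rho = 0.371 (exact permutation p = 0.497, adjusted 0.622), and r = −0.664 without those 2 libraries. Cell cycle genes stood at r = 0.877 (exact permutation p = 0.0222, adjusted 0.0370) and rho = 0.771 (exact permutation p = 0.103, adjusted 0.147), but at r = 0.260 without those 2 libraries, on which the relation rests. Smooth muscle markers stood at r = 0.799 (exact permutation p = 0.0653, adjusted 0.0933), rho = 0.771 (exact permutation p = 0.103, adjusted 0.147) and r = 0.909 without those 2 libraries, and endothelial markers at r = −0.433 (exact permutation p = 0.375, adjusted 0.469), rho = −0.314 (exact permutation p = 0.564, adjusted 0.627) and r = 0.0941.

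Control 35 had the highest values of atrial muscle genes: Myl7 was 11.3 times its level in control 37 (134 CPM), and stood at 37.7 CPM in TFEB 43, 7.69 in TFEB 41, 0.421 in control 36 and 0.127 in TFEB 34. A stress programme of ventricular muscle is argued against, since control 35 was not the highest library for Nppb, Ankrd1 or Myh7: Nppb stood at 82.1 CPM there and 503 CPM in TFEB 34. Nppa, which atria also make, was highest in control 35 (13805 CPM); Nppa, Nppb, Myh7, Myl4, Sln and Mybphl were chosen after their values were seen. Over the 6 libraries Myl7 and Nppb had a Spearman's rho of −0.771 (exact permutation p = 0.103) and a Pearson's r of −0.416 (exact permutation p = 0.438), or −0.963 without the 2 libraries farthest from the median of Myl7. Atrial muscle in the tissue taken stays open: in the 4 libraries with at least 50 Myl7 counts, the ratio to Myl7 varied 1.14 times for Myl4, 2.096 times for Sln and 2.20 times for Mybphl, where a bound of 2 had been set, with the largest departures in TFEB 41, which had few counts of these genes.

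The lysosome list was higher in TFEB overexpression only at the preset correlation, with a median log2 fold change of 0.09. With the matrix level as a covariate, shared members left out, the median was 0.039 (quartiles −0.046 and 0.13), 36 of 59 members had a higher value in place of 44, and limma's camera gave an adjusted p of 0.0884. With the atrial level as a further covariate the median was 0.063, 47 of 59 members had a higher value, and camera called the list again at the preset correlation (adjusted p = 0.00445), and not with an estimated one (adjusted p = 0.894 with an estimated correlation). The fits point different ways, and both covariates were made from these same libraries, which leaves little to estimate the spread. At the preset correlation 10 of the 10 splits of the libraries gave as many list calls as the real split. Such a call therefore does not set a group effect apart from chance. Spread in matrix content, an effect of TFEB on these genes and chance all stay open. Macrophage markers, a list that shares Gpnmb with the lysosome list, also went with the matrix level (Pearson's r = 0.979). Their level was not used as a covariate, so a part of macrophages in the lysosome values was not tested.

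Single hypotheses were tested as follows. Fat in the tissue taken may account for the adipocyte genes. Fat content that varies for any reason makes such genes correlate, so this test cannot tell dissection from an effect of genotype on fat. In it, 8 other adipocyte genes had a median Spearman's rho of 0.80 with Adipoq over the 6 libraries. Of these, 4 did not pass the expression filter (Lep, Retn, Acvr1c and Adrb3, with 71 to 120 counts in total), and over the 4 that did the median was 0.657, with Cidea and Plin4, singled out after their values were seen, at 0.543. For the lower values of Ddit4, Depp1 and Dusp1, lower glucocorticoid signalling is a candidate explanation: the median log2 fold change of 13 other response genes was −0.29, with 11 lower, but Fkbp5 stood at 0.23 and Zbtb16 at 0.10, both singled out after their values were seen, and 1 of the 9 other splits of the libraries gave a median farther from 0, of −0.45. A different time of day was not decided, since the Arntl phase genes stood at a median of −0.27 and the Dbp phase genes at 0.18, a difference of −0.45. Depp1, Timp4 and Cidec lie within 10 Mb of the Rosa26 locus on chromosome 6, and 4 of the 107 tested genes there had an unadjusted p under 0.05, or 3.74%, against 1.19% elsewhere (one-sided Fisher's exact p = 0.0408). Strain sequence carried along with the targeted locus could give such differences, but those 3 genes had been seen before the test, and without them the share was 0.962% (one-sided Fisher's exact p = 0.713).

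With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. edgeR called 0 genes in the real split and at most 0 in the others, so 10 of the 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 164 genes, 7 of the 10 splits gave as many, and the highest other gave 3507. Camera at the preset correlation called 7 lists in the real split, 10 of the 10 splits gave as many, and the highest other gave 16. The split with 3507 genes set controls 35 and 37 and TFEB 43 against the rest, which points to a structure of the samples along the matrix axis.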
